A study of Homo sapiens with 36 samples.

How the data were processed

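RNA was sequenced from 36 cultures: JEG-3 cells (20 libraries, 5 in each of 4 groups) and CD14-selected decidual macrophages (16 libraries, 4 in each of 4 groups), either untreated or kept for 24 h with vehicle, 1 nM or 1000 nM melatonin. The series' broader study also used a bacterial lipopolysaccharide stimulus, per the labels, but none of these libraries carries that treatment in its label. Groups and replicate numbers were taken from the titles and treatment labels. The labels call the samples biological replicates without saying which cultures or donors they came from. The p-values thus measure the spread between these samples, part of which may be technical. Each fit estimated the spread of a gene over all its groups, so a p-value also draws on groups that are not compared.

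The authors deposited gene counts for all 36 libraries in a single table of whole numbers, not normalized. Per the labels' protocols, libraries were strand-specific, from polyadenylated RNA, and a BGISEQ instrument read both ends of each fragment. Per the submitters' processing notes, the tools were STAR 2.7, featureCounts and DESeq2, with the genome build GRCh38.p13. The gene annotation, the featureCounts settings and any filter on the genes in the table are not given in the sources used here. The table held 14487 gene symbols, of which 14299 matched a RefSeq symbol. XIST, TSIX and Y-linked genes, 10 in all, were left out, which kept 14477. Totals were 17007709 to 19606163 counts per library in JEG-3 and 19091323 to 19756626 in macrophages, with 13153 to 14353 and 14194 to 14436 genes at 1 count or more. A level of 1 CPM (counts scaled to library size) is then fewer than 20 reads per library, so values below it rest on a handful of reads.

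Within groups, 64 pairs of libraries were compared by a chi-square test of their counts over genes; 0 agreed within sampling noise (lowest chi-square per degree of freedom 4.38), so each library counted as its own sample.

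Genes with enough counts were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and each comparison was tested with edgeR's robust quasi-likelihood F test over all 4 groups of a cell type, with no block. Comparisons between cell types and the interactions used a fit of all 8 groups. Changes are log2 fold changes with a standard error (SE), p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene passed at an adjusted p below 0.05. Levels are CPM with the SD over libraries. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9. Gene positions came from GENCODE 29 on GRCh38, by symbol.

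The replicate numbers pair the samples. After group means were removed, the 24 pairs of macrophage libraries with the same number correlated at 0.629 or more (median 0.802), and 16 of 16 libraries correlated best with their own number; in JEG-3 the 30 pairs correlated at 0.839 or more, and 20 of 20 did (24 pairs at 0.760 or more, and 14 of 16, without the discordant libraries). Between libraries of different numbers the highest correlation was 0.297 in macrophages, 0.910 in JEG-3 and 0.885 in JEG-3 without the discordant libraries. In JEG-3 it lies above the lowest correlation within a number, so the pairing is less clear there. The pairing rests on this check, as the labels do not say what a number stands for. Results of a fit with the number as a block are printed where they change a call or move a count by more than 1.5 times.

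There were 31 gene lists, chosen before the data were examined: inflammasome, NF-kB inflammatory genes, NRF2 targets, antioxidant enzymes, the melatonin system, aryl hydrocarbon receptor targets, circadian clock, nuclear respiratory chain, mitochondrially encoded genes, glycolysis, hypoxia, unfolded protein response, heat shock, interferon response, cholesterol synthesis, cell cycle, immediate early genes, apoptosis and p53, lysosome and autophagy, metallothioneins, ribosomal proteins, macrophage identity, alternative activation, MHC class II, trophoblast identity, decidual stroma, endothelium, T and natural killer cells, B and plasma cells, neutrophils and red cells. Each was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 members tested, and again with an estimated correlation. Many members of lists for other cell types were detected: in macrophage libraries 14 of 14 stroma and 12 of 28 trophoblast genes reached 10 CPM, and 1 of 15 T and natural killer cell markers did. Whether the macrophages or other cells in the preparations expressed them was not tested.

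Named genes followed a rule set before the data were examined: up to 12 in each direction with the largest absolute log2 fold change among those that passed with a mean of at least 1 CPM (50 CPM between cell types); where fewer than 5 passed, the same rule on the block fit, and then the 5 genes with the smallest p; 12 preset genes (NLRP3, CASP1, IL1B, IL18, PYCARD, GSDMD, NFE2L2, HMOX1, NQO1, GCLM, TXNRD1 and SOD2); and up to 4 members per list. A part of the genes this gives is printed. Genes with common germline deletions are not named. CXCL8 was added to a plot of levels after its values were seen. MTNR1A and MTNR1B, the melatonin receptors, were not analysed here.

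The fits were tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. For macrophages (13680 genes) 26 and 72 were recovered, and 84 and 98 with the block, with 4 unchanged genes called in each. For JEG-3 (12285 genes) 2 and 34 were recovered, 85 and 100 with the block, and 60 and 92 without the discordant libraries; 0, 14 and 10 unchanged genes were called. For the interaction (14246 genes) 4 and 37 were recovered with 3 unchanged genes called. DESeq2 without the block recovered 51 and 85 for macrophages, with 39 unchanged genes called. For JEG-3 it recovered 12 and 63, with 33 called. Its counts may thus hold more false calls than those of edgeR.

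Alternatives were DESeq2 size factors, DESeq2's Wald test, no filter on low counts, the replicate block, only the groups compared, untreated or the mean of both controls in place of vehicle, an added minimum absolute log2 fold change of 1, and leaving out each library. Similarity of the doses was set against 20 simulated data sets of unchanged groups per cell type and against splits of the vehicle libraries. Neither kept the pairing of libraries by replicate number.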

Results

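Gene expression was measured by RNA sequencing in JEG-3 cells, a human choriocarcinoma line widely used as a stand-in for placental trophoblast, and in CD14-selected macrophages from human decidua, the maternal tissue that borders the placenta. Each cell type was kept for 24 h without treatment, with the diluent alone (vehicle), or with the pineal hormone melatonin at 1 nM or 1000 nM. There were 5 libraries per group for JEG-3 and 4 per group for macrophages, which gave 36 libraries in 8 groups. Library totals ran from 17007709 to 19606163 counts in JEG-3 and from 19091323 to 19756626 in macrophages, over 14487 genes. The study's title names inflammasome and antioxidant genes as its subject, and the comparisons below ask how those genes and the rest of the transcriptome differed between melatonin, vehicle and no treatment in each cell type.

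Of the 20 libraries labelled JEG-3, 4 did not match their label, 1 in each treatment group. For 46 genes abundant in the other JEG-3 libraries and under 1 CPM (counts scaled to library size) in macrophages, the median level in each of these 4 discordant libraries was between 0.259 and 0.435% of the JEG-3 level. For 429 genes abundant in macrophages and under 1 CPM in the other JEG-3 libraries, it was between 79.0 and 97.8% of the macrophage level. None of the 16 libraries labelled macrophage was closer to JEG-3. The discordant libraries stayed in the planned JEG-3 comparisons, and JEG-3 counts of genes and lists are also given without them. The other 16 JEG-3 libraries formed 2 subsets that cut across the treatments, replicates 1 and 4 against 2 and 3. Mean log2 CPM of hypoxia genes ran from 4.07 to 4.29 in the first and from 6.34 to 6.61 in the second. Chi-square per degree of freedom between libraries of a group was 4.38 to 45.3 within subsets and 115 to 183 between them. What the subsets stand for is not in the labels, and this spread stays in JEG-3 fits without the block.

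In decidual macrophages the libraries labelled vehicle differed from untreated ones by a broad rise of inflammatory genes. SOD2, the mitochondrial superoxide dismutase, rose from 2202 ± 268 to 10579 ± 4311 CPM (SD, n = 4 per group; log2 fold change 2.25 ± 0.27 SE, adjusted p = 0.00123). NLRP3, the sensor protein of the best studied inflammasome, rose from 34.5 ± 3.58 to 81.5 ± 26.2 CPM (log2 fold change 1.23 ± 0.21 SE, adjusted p = 0.00868). IDO1, which breaks down tryptophan, rose from 10.5 ± 4.45 to 649 ± 897 CPM (log2 fold change 5.91, adjusted p = 0.0061). Among the genes that fell, the fatty acid receptor FFAR4 went from 4.11 ± 3.16 to 0.22 ± 0.11 CPM (log2 fold change -4.20, adjusted p = 0.0141). CD180, a Toll-like receptor homologue, went from 51.9 ± 30.8 to 3.90 ± 2.30 CPM (log2 fold change -3.73, adjusted p = 0.0126). All of these went the same way in 4 of 4 replicate pairs. In the GRCh38 annotation of GENCODE 29, NLRP3 spans chromosome 1, 247416156 to 247449108, IL1B chromosome 2, 112829751 to 112836903, IDO1 chromosome 8, 39902275 to 39928444, and FFAR4 chromosome 10, 93566665 to 93604480. SOD2 spans chromosome 6, 159669057 to 159745186, and overlaps another entry with the same symbol on the same strand, so its count is less certain.

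Across all 13775 genes tested, 558 passed at an adjusted p below 0.05 for vehicle against untreated macrophages, 372 higher and 186 lower. With the replicate number as a block the count was 4349. Other genes with large rises were the cytokine IL1A (log2 fold change 5.11), the chemokine CCL4 (5.89), the homing receptor CCR7 (5.15), the interferon-induced OASL (5.69) and the co-receptor SLAMF1 (5.12). TNF rose by a log2 fold change of 6.33, with an adjusted p of 0.0319, which was 0.0504 with the block. IFIT2, another interferon-induced gene, rose by 5.45 with an adjusted p of 0.0491, against 0.0741 with the block. CCL3L1, CCL3L3 and CCL4L2 rose too (6.27, 5.42 and 5.62), but these are near-identical gene copies whose reads cannot be assigned with certainty. Genes that fell included the receptor CD300LB (-2.49), the folate carrier SLC46A1 (-2.36), the myeloid transcription factor CEBPA (-2.28), the sugar phosphate transporter SLC37A2 (-2.05) and the fatty acid binding protein FABP3 (-2.98).

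The preset inflammasome list had 21 members tested in macrophages. NLRP3, MEFV (pyrin, 2.25), CASP4 (0.80) and CASP5 (3.54), the last a pair of inflammatory caspases, rose, none fell and 17 did not pass, while 6 rose when adjusted over the list alone. With the block 9 rose and 2 fell. The list as a whole was higher in vehicle (adjusted p = 2.16e-05, and adjusted p = 0.033 with an estimated correlation, or 0.109 with the block as well). IL1B, the cytokine that inflammasomes mature, stood at 7024 ± 6415 CPM in vehicle and 241 ± 233 untreated, which did not pass without the block (log2 fold change 4.84 ± 1.45 SE, adjusted p = 0.0777) and passed with it (6.30, adjusted p = 0.00252). CASP1 (0.54, adjusted p = 0.321) and IL18 (0.63, adjusted p = 0.324) did not pass in either fit. The adaptor PYCARD (-0.86, adjusted p = 0.295) and the pore protein GSDMD (0.37, adjusted p = 0.541) passed only with the block, at 0.00558 and 0.0222.

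Of 24 cytokine, chemokine and feedback genes of NF-kB signalling, 13 rose and 22 rose when adjusted over the list alone, with a list median log2 fold change of 3.56 (adjusted p = 4.26e-22, but adjusted p = 0.159 with an estimated correlation). NFKBIA (2.15), NFKB2 (1.94), RELB (1.23) and the adhesion molecule ICAM1 (1.78) were among them. Of 25 interferon response genes, 13 rose and 23 rose when adjusted over the list alone (median 2.24, adjusted p = 3.64e-16, but adjusted p = 0.281 with an estimated correlation), including IFIT3 (4.26) and the RNA sensors DDX58 (3.77) and IFIH1 (2.79). Of 8 metallothionein genes, 3 rose and 7 rose when adjusted over the list alone (median 3.22, adjusted p = 3.54e-07, but adjusted p = 0.281 with an estimated correlation), with MT1M at 4.88, MT1F at 3.62 and MT1X at 2.82. Of 17 immediate early genes, JUNB (0.92), NR4A3 (2.58) and IER3 (2.51) rose, also when adjusted over the list alone, and the list was called higher (adjusted p = 1.48e-04, but adjusted p = 0.372 with an estimated correlation). With the block 22 of the NF-kB genes, 24 of the interferon genes, 7 of the metallothioneins and 11 of the immediate early genes rose. The mean log2 CPM of the NF-kB list rose in 4 of 4 replicate pairs, by 1.39 to 4.57. On it 1 vehicle and 1 untreated library, of different replicate numbers, stood apart from their groups. Without them, and with their pair partners kept, the difference was 1.49, against 2.78 with all. The interferon mean rose in 3 of 4 pairs (-0.075 to 3.64).

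Neither antioxidant list was called for vehicle against untreated. Of 23 NRF2 target genes, NFE2L2, which encodes NRF2 itself (0.84, adjusted p = 0.0437), and the exporter ABCC1 (0.64, adjusted p = 0.0462) rose, 21 did not pass, and 2 rose when adjusted over the list alone (list adjusted p = 0.314). Of 22 antioxidant enzymes SOD2 alone rose without the block, over all genes and when adjusted over the list alone (list adjusted p = 0.426). With the block 8 NRF2 targets rose and 6 fell, and 2 antioxidant enzymes rose and 5 fell. HMOX1, haem oxygenase 1 (-0.45, adjusted p = 0.334), and the glutathione synthesis gene GCLM (0.36, adjusted p = 0.629) and thioredoxin reductase TXNRD1 (0.36, adjusted p = 0.635) passed only with the block, at 0.0304, 0.0126 and 0.00266. NQO1 did not pass in either fit (0.34, adjusted p = 0.696, and 0.0593 with the block). Catalase (CAT) was lower by a log2 fold change of -0.86 at an adjusted p of 0.0958, and passed with the block (1.73e-04).

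Of the remaining lists in this comparison, 5 were called and none held with an estimated correlation. Aryl hydrocarbon receptor targets were higher (0 of 5 members passing, 2 when adjusted over the list alone; adjusted p = 0.0134, and adjusted p = 0.159 with an estimated correlation). So were hypoxia genes (1 of 14, PFKFB3 at 1.79, and 2 when adjusted over the list alone; adjusted p = 0.0216, and adjusted p = 0.503 with an estimated correlation). T and natural killer cell markers were higher as a list (1 of 15, the perforin gene PRF1 at 1.61, also when adjusted over the list alone; adjusted p = 0.00287, and adjusted p = 0.47 with an estimated correlation). Nuclear genes of the respiratory chain (0 of 33, also when adjusted over the list alone; median -0.27, adjusted p = 3.64e-04, and adjusted p = 0.858 with an estimated correlation) and ribosomal proteins (0 of 36, also when adjusted over the list alone; median -0.21, adjusted p = 5.36e-04, and adjusted p = 0.858 with an estimated correlation) were lower. Among lists that were not called, the circadian clock list had BHLHE40 higher (0.61) and DBP (-2.60) and TEF (-0.97) lower of 19, with 1 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.87). With the block 4 aryl hydrocarbon receptor targets, 6 hypoxia genes, 9 T and natural killer cell markers and 6 clock genes were higher. With it 12 respiratory chain genes, 4 clock genes and 1 hypoxia gene were lower, and 0 ribosomal proteins passed. The means of the respiratory chain and ribosomal lists fell in 3 of 4 pairs each.

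Further lists were not called and had at most 3 members passing without the block. Members that rose were IDO1 of 6 melatonin pathway genes (list adjusted p = 0.702), HK2 (1.24) of 18 glycolysis genes (0.534), PPP1R15A (1.18) of 16 unfolded protein genes (0.801), LSS (1.43) of 23 cholesterol synthesis genes (0.946), CD80 (2.65) of 14 genes of MHC class II and costimulation (0.825), and CASP3 (0.68) and MCL1 (0.90) of 20 apoptosis and p53 genes (0.307). HSPE1 (-0.70) of 11 heat shock genes (0.314) and ZMAT3 (-0.92) of the apoptosis genes fell. When adjusted over the list alone, 2 heat shock genes fell, 5 apoptosis genes rose and 2 fell, and the other counts stayed at 1. Without the block no member passed among 26 cell cycle (list adjusted p = 0.41), 18 lysosome and autophagy (0.68), 22 macrophage identity (0.233), 16 alternative activation (0.466), 26 trophoblast (0.825), 14 decidual stroma (0.809), 8 endothelial (0.87), 5 neutrophil (0.233) and 4 red cell genes (0.611). Adjusted over the list alone, 1 alternative activation gene rose and 1 fell, 2 neutrophil genes fell and the others stayed at 0. The block gave calls both ways in most of these lists. Higher and lower were 1 and 6 macrophage identity, 4 and 6 alternative activation, 1 and 6 lysosome, 0 and 3 cell cycle, 1 and 3 trophoblast, 2 and 0 stroma, 2 and 1 endothelial, 0 and 2 neutrophil, and 0 and 0 red cell genes. They were 2 and 3 melatonin pathway, 3 and 3 glycolysis, 4 and 3 unfolded protein, 3 and 4 cholesterol, 2 and 3 MHC class II, 6 and 3 apoptosis, and 2 and 3 heat shock genes. None of these lists was called with the block. Mitochondrially encoded genes had 0 of 13 members in the table, and B and plasma cell markers 3 of 7, too few tested for a list test.

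The size of the gene count depended on which libraries entered. It was 332, 228, 105 and 129 without untreated replicate 1, 2, 3 and 4. With only the vehicle and untreated groups in the fit it was 10. That fit has fewer libraries and takes no spread from the melatonin groups. Which of these lowered the count was not tested. Of 52 named genes that passed, 15 passed in every fit without 1 library, among them NLRP3, SOD2, IDO1, SLAMF1, FFAR4, CD180, CASP5, MEFV, RELB and NFKBIA. DESeq2 called 1348 genes.

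**Figure D1:**
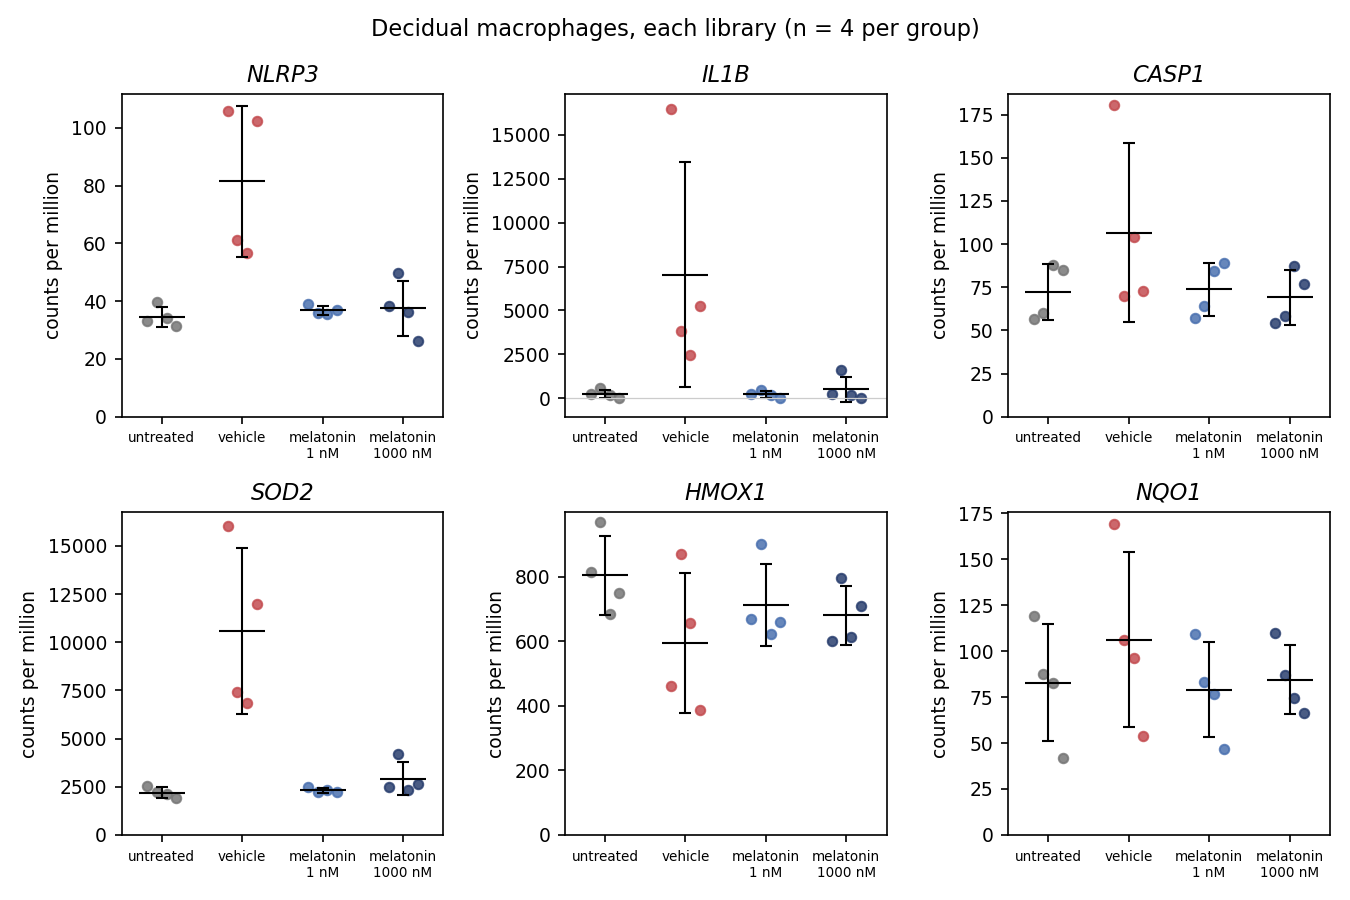
Level in CPM of NLRP3, IL1B, CASP1, SOD2, HMOX1 and NQO1 in each decidual macrophage library (points) of the 4 groups, with the mean (line) and SD (bars, n = 4). The libraries labelled vehicle lie above the other groups for NLRP3 (mean 81.5) and SOD2 (mean 10579), while those of HMOX1 and NQO1 overlap with the other groups.

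With melatonin at 1 nM, macrophages had lower inflammatory transcripts than the libraries labelled vehicle, at levels near the untreated ones. SOD2 stood at 2310 ± 116 CPM against 10579 ± 4311 in vehicle (SD, n = 4 per group; log2 fold change -2.18 ± 0.27 SE, adjusted p = 0.00163), and NLRP3 at 36.9 ± 1.51 against 81.5 ± 26.2 (log2 fold change -1.14 ± 0.21 SE, adjusted p = 0.0137). IDO1 was lower by a log2 fold change of -5.80 (adjusted p = 0.00692) and the growth factor EREG by -4.96 (adjusted p = 0.0299). FFAR4 was higher at 4.25 ± 2.93 against 0.22 ± 0.11 CPM (log2 fold change 4.24, adjusted p = 0.0141), and CD180 at 54.1 ± 33.5 against 3.90 ± 2.30 CPM (log2 fold change 3.78, adjusted p = 0.0128). These 6 genes went the same way in 4 of 4 replicate pairs.

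Other genes lower at 1 nM than in vehicle were CCL4 (-5.75), CCL3 (-4.87), CCR7 (-5.16), IL1A (-5.15), SLAMF1 (-4.81) and MT1M (-5.13). TNF was lower by a log2 fold change of -6.28 with an adjusted p of 0.0338, against 0.0579 with the block. Higher ones were CD300LB (2.56), SLC46A1 (2.34), CEBPA (2.19), the coactivator PPARGC1B (2.03) and the efflux transporter ABCG2 (1.85). Of the inflammasome list, NLRP3, MEFV (-2.15), CASP4 (-0.78) and CASP5 (-3.95) were lower, 17 of 21 did not pass, and 6 were lower when adjusted over the list alone (list adjusted p = 4.32e-05, and adjusted p = 0.0386 with an estimated correlation, or 0.137 with the block as well). With the block 2 were higher and 9 lower. IL1B stood at 213 ± 189 CPM, which did not pass against vehicle without the block (-5.02, adjusted p = 0.0753) and passed with it (-6.36, adjusted p = 0.00262). CASP1 (-0.51, adjusted p = 0.363) and IL18 (-0.68, adjusted p = 0.29) did not pass in either fit, and PYCARD (0.63, adjusted p = 0.494) and GSDMD (-0.35, adjusted p = 0.59) passed only with the block, at 0.0252 and 0.0272.

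Neither antioxidant list was called at 1 nM. Without the block 0 of 23 NRF2 targets passed (1 lower when adjusted over the list alone; list adjusted p = 0.221), and SOD2 was the antioxidant enzyme that passed, 1 of 22 and also when adjusted over the list alone (list adjusted p = 0.798). With the block 4 NRF2 targets were higher and 10 lower, and 4 antioxidant enzymes were higher and 2 lower. NFE2L2 (-0.82, adjusted p = 0.0526), NQO1 (-0.41, adjusted p = 0.621), GCLM (-0.42, adjusted p = 0.573) and TXNRD1 (-0.37, adjusted p = 0.641) passed only with the block, at 5.84e-04, 0.0348, 0.00764 and 0.00259. HMOX1 did not pass in either fit (0.27, adjusted p = 0.647, and 0.166 with the block).

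Of the NF-kB list, 12 of 24 were lower at 1 nM and 22 when adjusted over the list alone (median -3.69, adjusted p = 3.28e-22, but adjusted p = 0.245 with an estimated correlation), with RELB (-1.28) and NFKBIA (-2.09) among them. Of the interferon list, 3 of 25 were lower, such as IFIH1 (-2.53), and 23 when adjusted over the list alone (adjusted p = 3.89e-13, but adjusted p = 0.343 with an estimated correlation). Metallothioneins (3 of 8 lower, 7 when adjusted over the list alone; adjusted p = 1.23e-07, but adjusted p = 0.273 with an estimated correlation) and immediate early genes (3 of 17 lower, 4 when adjusted over the list alone; adjusted p = 6.57e-05, but adjusted p = 0.343 with an estimated correlation) were lower too. Hypoxia genes (adjusted p = 0.0178, and adjusted p = 0.419 with an estimated correlation), aryl hydrocarbon receptor targets (0.0338, and adjusted p = 0.25 with an estimated correlation) and T and natural killer cell markers (0.00332, and adjusted p = 0.419 with an estimated correlation) were lower as lists. Respiratory chain genes were higher (0.0205, and adjusted p = 0.938 with an estimated correlation). HK2 (-1.18) and LSS (-1.48) fell in lists that were not called. With the block 22 NF-kB, 17 interferon, 7 metallothionein, 11 immediate early, 6 hypoxia, 3 aryl hydrocarbon receptor and 7 T and natural killer cell genes were lower. With it 11 respiratory chain genes and 1 hypoxia gene were higher. By pair, the interferon mean was lower in 3 of 4 (-3.74 to 0.76), the respiratory chain mean higher in 3 of 4 and the NF-kB mean lower in 4 of 4. Without the vehicle library and the 1 nM library that stood apart, and with their pair partners kept, the NF-kB difference was -1.55, against -2.69 with all.

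In all, 461 genes passed for 1 nM against vehicle, 161 higher and 300 lower, and 4151 with the replicate block. DESeq2 called 1290. Without 1 nM replicate 1, 2, 3 and 4 the count was 268, 188, 90 and 120, and with only these 2 groups in the fit it was 12. Of 26 named genes that passed, 11 passed in every fit without 1 library, among them SOD2, IDO1, FFAR4, CD180, CASP5, RELB and NFKBIA. Against untreated macrophages in place of vehicle, melatonin at 1 nM gave 0 genes by edgeR (2 at an unadjusted p below 0.05), and 0 with the block (113); DESeq2 was not run with that control. NLRP3 then differed by 0.09 ± 0.21 SE, SOD2 by 0.066 ± 0.26 SE and IL1B by -0.18 ± 1.24 SE on the log2 scale. Against untreated 4 lists were called at 1 nM. Interferon genes were higher (median 0.36, adjusted p = 8.59e-07, but adjusted p = 0.99 with an estimated correlation), with the list mean higher in 3 of 4 pairs (-0.099 to 0.68). Antioxidant enzymes (median -0.069, adjusted p = 0.0464), respiratory chain genes (-0.091, adjusted p = 4.90e-06) and ribosomal proteins (-0.086, adjusted p = 1.04e-08) were lower, each in 4 of 4 pairs and with adjusted p = 0.99 with an estimated correlation. These 4 lists had 0 members passing.

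Macrophages given 1000 nM melatonin differed from the libraries labelled vehicle in the same direction as at 1 nM for the genes named here. SOD2 stood at 2917 ± 866 CPM (SD, n = 4; log2 fold change -1.84 ± 0.27 SE against vehicle, adjusted p = 0.00689) and NLRP3 at 37.6 ± 9.54 CPM (-1.11 ± 0.21 SE, adjusted p = 0.0244). IL2RA, the interleukin 2 receptor alpha chain, was lower at 26.0 ± 9.09 against 252 ± 215 CPM (log2 fold change -3.25 ± 0.48 SE, adjusted p = 0.00761), as were the chemokine CCL8 (-3.83, adjusted p = 0.0243) and IDO1 (-5.67, adjusted p = 0.0138). CD300LB was higher at 16.1 ± 5.36 against 2.98 ± 1.42 CPM (2.43 ± 0.34 SE, adjusted p = 0.0058). Each went the same way in 4 of 4 replicate pairs.

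FFAR4 (3.91), CD180 (3.49), SLC46A1 (2.21), CEBPA (2.06), ABCG2 (1.74) and the reduced folate carrier SLC19A1 (1.51) were also higher, and CCR7 (-5.18), SLAMF1 (-4.25), GCH1, the entry enzyme of biopterin synthesis (-3.90), and the vasoconstrictor EDN1 (-2.90) lower. Of the inflammasome list, NLRP3, MEFV (-2.17), CASP4 (-0.78) and CASP5 (-2.87) were lower, 17 of 21 did not pass, and 7 were lower when adjusted over the list alone (list adjusted p = 1.81e-05, and adjusted p = 0.0255 with an estimated correlation, or 0.0764 with the block as well). With the block 1 was higher and 8 lower. IL1B stood at 506 ± 725 CPM and did not pass without the block (-3.76, adjusted p = 0.181), but did with it (-5.40, adjusted p = 0.00643). CASP1 (-0.61, adjusted p = 0.306), IL18 (-0.57, adjusted p = 0.44) and GSDMD (-0.27, adjusted p = 0.746) did not pass in either fit, and PYCARD (0.61, adjusted p = 0.557) passed only with the block, at 0.0319.

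At this dose SOD2 was again the antioxidant enzyme that passed, 1 of 22 and also when adjusted over the list alone (list adjusted p = 0.554), and 0 of 23 NRF2 targets did, also when adjusted over the list alone (list adjusted p = 0.318). NFE2L2 (-0.76, adjusted p = 0.0845), GCLM (-0.42, adjusted p = 0.61) and TXNRD1 (-0.34, adjusted p = 0.727) passed only with the block, at 0.00135, 0.0101 and 0.00581, while HMOX1 (0.20, adjusted p = 0.804) and NQO1 (-0.31, adjusted p = 0.786) did not. Of the NF-kB list, 4 of 24 were lower, such as RELB (-1.02) and NFKBIA (-1.76), and 22 when adjusted over the list alone (adjusted p = 2.18e-20, but adjusted p = 0.244 with an estimated correlation). CMPK2 (-2.49) was the interferon gene that passed of 25 without the block, and 23 were lower when adjusted over the list alone (adjusted p = 1.59e-19, but adjusted p = 0.244 with an estimated correlation). Metallothioneins had 0 of 8 passing and 7 lower when adjusted over the list alone (adjusted p = 4.37e-07, but adjusted p = 0.259 with an estimated correlation), and immediate early genes 0 of 17 and 3 (adjusted p = 5.22e-04, but adjusted p = 0.408 with an estimated correlation). Hypoxia genes (0.0186, and adjusted p = 0.442 with an estimated correlation) and T and natural killer cell markers (0.0013, and adjusted p = 0.408 with an estimated correlation) were lower as lists, respiratory chain genes higher (0.00779, and adjusted p = 0.849 with an estimated correlation). Calls for lower aryl hydrocarbon receptor targets (0.0472, and adjusted p = 0.244 with an estimated correlation) and higher ribosomal proteins (0.0368, and adjusted p = 0.964 with an estimated correlation) were lost with the block. With the block 19 NF-kB, 24 interferon, 7 metallothionein, 8 immediate early, 6 hypoxia and 8 T and natural killer cell genes were lower, and 9 respiratory chain genes and 1 hypoxia gene higher. Of the NRF2 targets 2 were then higher and 8 lower, and of the antioxidant enzymes 4 higher and 2 lower. By pair, the NF-kB and interferon means were lower in 4 of 4, and the respiratory chain and ribosomal means higher in 3 of 4. Without the vehicle library that stood apart, and with its pair partner kept, the NF-kB difference was -1.57, against -2.36 with all.

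At 1000 nM 202 genes passed against vehicle, 62 higher and 140 lower, and 3596 with the replicate block; DESeq2 called 975. The count was 27, 21 and 25 without 1000 nM replicate 1, 3 and 4, and 0 with only these 2 groups in the fit by edgeR; of 24 named genes that passed, CD300LB, IL2RA and SOD2 passed in every fit without 1 library. Against untreated macrophages it gave 0 genes by edgeR (4 at an unadjusted p below 0.05), and 0 with the block (145). DESeq2 was not run with that control. Against untreated 7 lists were called. NF-kB genes (median 0.35, adjusted p = 3.77e-09) were higher, but their mean rose in 3 of 4 pairs. The difference of 0.42 was -0.076 without the untreated library that stood apart, which parts a pair and so cannot settle the sign. Also higher were metallothioneins (0.47, adjusted p = 0.0219, lost with the block), aryl hydrocarbon receptor targets (0.15, adjusted p = 0.0364) and immediate early genes (0.096, adjusted p = 0.0364), whose means rose in 4, 3 and 2 of 4 pairs. Respiratory chain genes (-0.059, adjusted p = 1.09e-04), cholesterol synthesis genes (-0.12, adjusted p = 0.049) and ribosomal proteins (-0.082, adjusted p = 3.75e-08) were lower, and so with the block were macrophage identity genes (-0.11, adjusted p = 0.0173, and adjusted p = 0.781 with an estimated correlation). Each had 0 members passing, and with an estimated correlation adjusted p was 0.62 for aryl hydrocarbon receptor targets and 0.957 for the other 6 without the block. The means of the respiratory chain and ribosomal lists were lower in 3 of 4 pairs and that of cholesterol synthesis in 1 of 4.

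**Figure D2:**
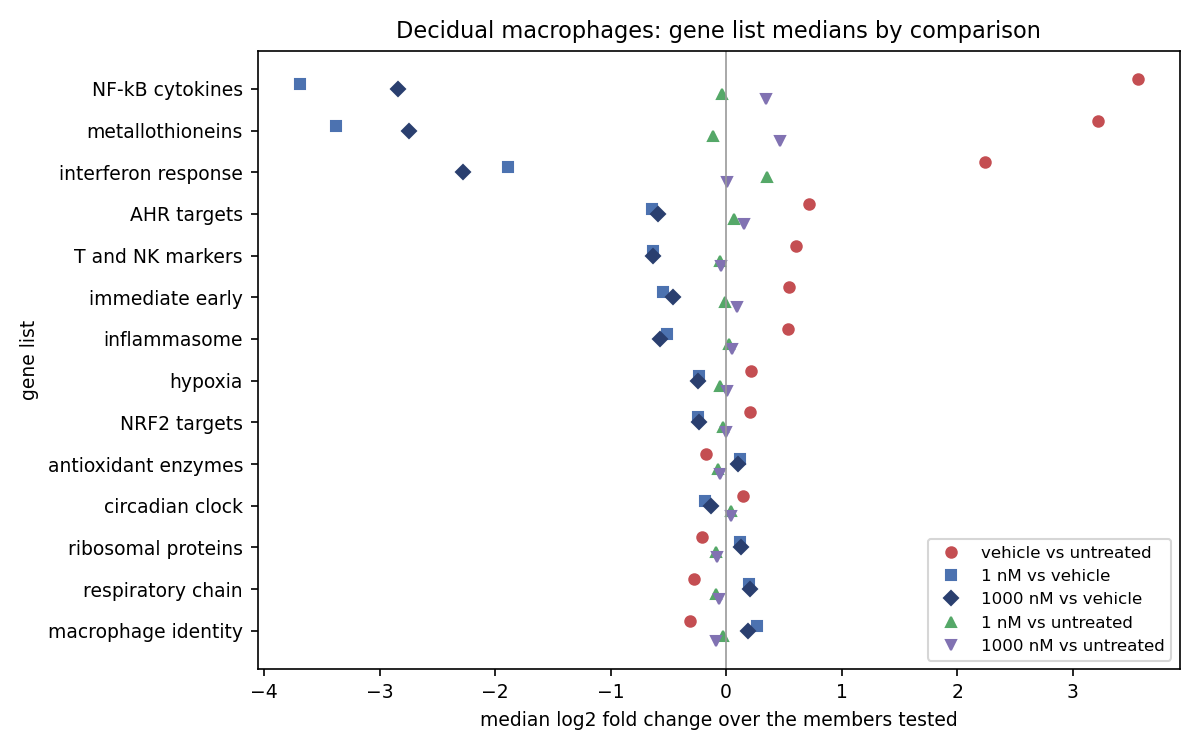
Median log2 fold change over the tested members of 14 gene lists (rows) in decidual macrophages, for vehicle against untreated (circles), melatonin against vehicle at 1 nM (squares) and 1000 nM (diamonds), and melatonin against untreated (triangles). The NF-kB list stands at 3.56 for vehicle against untreated and at -3.69 for 1 nM against vehicle. For melatonin against untreated the NF-kB median at 1000 nM (0.35) and the interferon median at 1 nM (0.36) lie above 0, although the mean of each list rose in only 3 of 4 pairs. The NF-kB difference in mean turned from 0.42 to -0.076 without 1 untreated library, whose pair partner at 1000 nM stayed in.

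The doses were compared directly to ask whether the response grew with concentration. No gene passed between 1000 and 1 nM in macrophages by edgeR (3 at an unadjusted p below 0.05), with the block (83) or by DESeq2. NLRP3 differed by 0.030, IL1B by 1.26, SOD2 by 0.34, NFE2L2 by 0.064 and HMOX1 by -0.067 on the log2 scale, none passing. The NF-kB list (median 0.28, adjusted p = 2.84e-08), immediate early genes (adjusted p = 0.00658) and metallothioneins (adjusted p = 0.00239, lost with the block) were called higher and the interferon list lower (median -0.30, adjusted p = 2.84e-08) at 1000 nM. Each had 0 members passing and an adjusted p = 0.862 with an estimated correlation. The NF-kB mean was higher in 4 of 4 pairs, by 0.034 to 0.81. Its difference of 0.33 was -0.015 without the 1 nM library that stood apart. That parts a pair whose 1000 nM library also scored low (4.86), so it cannot settle the sign. The interferon mean was lower in 3 of 4 pairs (-0.85 to 0.067).

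Of the genes higher than vehicle in macrophages, 161 at 1 nM and 62 at 1000 nM, 61 were shared, where independent lists would share 0.725. Of those lower, 300 and 140, 139 were shared, against 3.05. Both doses were set against the same vehicle libraries, which raises the overlap above that of independent lists, and no overlap was simulated. Across the 13775 genes, which are not independent replicates, the fold changes of the doses correlated at r = 0.971 with a covariance of 0.367. Unchanged groups simulated with a shared vehicle group and no replicate effect gave r = 0.503 and a covariance of 0.108. Differences between replicate numbers count as noise there, which raises that covariance above what unchanged paired libraries would give. With the vehicle libraries split between the doses r was 0.358 and the covariance 0.172. Taking untreated libraries as the control of 1 dose and vehicle as that of the other gave r = -0.098 or -0.348. With untreated as the control of both doses r was 0.534 and the covariance 0.0135, where sharing the untreated libraries adds to both and no unchanged groups were simulated against them. Of the 372 genes higher in vehicle than untreated, 289 were among the 300 lower at 1 nM than in vehicle, against 8.10 for independent lists; these comparisons share the vehicle libraries.

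In JEG-3 cells no treatment comparison of all 20 labelled libraries gave a gene without the replicate block, in a fit that recovered 2 of 100 genes simulated to change 2-fold. In the 16 libraries with a JEG-3 profile SOD2 stood at 67.3 ± 27.0 CPM untreated (SD, n = 4), and HMOX1 at 3.71 ± 1.42. NLRP3 was near the detection limit at 0.763 ± 0.353 CPM untreated, 0.688 ± 0.213 with vehicle, 0.738 ± 0.106 at 1 nM and 0.892 ± 0.317 at 1000 nM. RSAD2, an interferon-induced antiviral gene on chromosome 2, 6865806 to 6898239, stood at 2.03 ± 0.38 CPM in vehicle and 0.20 ± 0.20 untreated, 0.375 ± 0.18 at 1 nM and 0.239 ± 0.07 at 1000 nM.

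For vehicle against untreated JEG-3, 0 of 12340 genes passed by edgeR (192 at an unadjusted p below 0.05) and 0 by DESeq2. With the replicate block 7 passed: RSAD2 (log2 fold change 3.40), the signalling adaptor TRAF1 (2.57), XIRP1 (2.54), the interleukin 1 antagonist IL1RN (2.28), the antiviral OAS2 (2.23) and the laminin chain LAMA3 (1.87) were higher and HLA-DMB (-1.62), which loads MHC class II, lower. Without the discordant libraries the block fit kept RSAD2 alone (3.33, adjusted p = 3.36e-04), TRAF1, XIRP1 and IL1RN no longer having enough counts to be tested. Of the preset genes, NLRP3 (1.38, and -0.14 without the discordant libraries), IL1B (0.18 and 3.56), SOD2 (-0.05 and 0.15), HMOX1 (0.35 and -0.08) and NQO1 (-0.20 and -0.014) did not pass in any of these fits, nor did IL18, GSDMD, NFE2L2, GCLM and TXNRD1. CASP1 and PYCARD had too few counts to be tested.

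For 1 nM against vehicle in JEG-3, 0 genes passed by edgeR (9 at an unadjusted p below 0.05) and by DESeq2, and 6 with the block: KCNJ5 (3.36), MPEG1 (2.96), A2M (2.35) and HLA-DMB (1.54) higher, IL1RN (-2.76) and RSAD2 (-2.48) lower. For 1000 nM, 0 passed by edgeR (10) and by DESeq2, and IL1RN (-2.10, adjusted p = 0.00859) and RSAD2 (-2.89, adjusted p = 7.78e-05) were lower with the block. Without the discordant libraries RSAD2 was the gene that passed with the block at both doses (-2.44, adjusted p = 0.00526, and -3.07, adjusted p = 6.94e-04). Between the doses 0 genes passed by edgeR (4), by DESeq2 or with the block; ZNF177 (1.10), SLC6A11 (0.69) and LETM2 (0.54) were among those with the smallest p and did not pass. Without the discordant libraries and without the block, edgeR called 0 genes for vehicle against untreated, 1 nM, 1000 nM and between doses, with 58, 33, 66 and 27 at an unadjusted p below 0.05; DESeq2 was not run on that set. Across genes the doses' fold changes against vehicle correlated at r = 0.851 with a covariance of 0.0799 (0.725 and 0.0264 without the discordant libraries). Unchanged groups simulated with a shared vehicle group and no replicate effect gave 0.50006 and 0.297 (0.502 and 0.0569). With the vehicle libraries split between the doses r was -0.503, and -0.0196 without the discordant libraries. Neither check kept the replicate pairing. Differences between numbers raise the simulated covariance and lower the r of the split, so these checks cannot tell whether the doses share an effect. With untreated as the control of both doses r was 0.904 and the covariance 0.13 with all libraries.

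Of 27 lists tested in JEG-3, 4, 6, 7 and 2 were called for vehicle against untreated, 1 nM, 1000 nM and between doses, with 0 members passing in any of them without the block, and with an estimated correlation 0 were called in each. With the discordant libraries left out 5, 6, 7 and 1 of 26 lists were called, and 2, 3, 1 and 0 with an estimated correlation. The block with all libraries called 7, 10, 9 and 5, and 6, 10, 9 and 4 without the discordant ones. With an estimated correlation as well it called NF-kB genes, lower, and alternative activation genes, higher, at 1 nM (adjusted p = 0.00283 and 0.0393 with an estimated correlation) and at 1000 nM (both adjusted p = 0.0366 with an estimated correlation). In vehicle against untreated, interferon genes were higher (adjusted p = 0.0341, and adjusted p = 0.986 with an estimated correlation) and antioxidant enzymes (8.79e-05), respiratory chain genes (1.51e-16) and ribosomal proteins (5.17e-11) lower, with adjusted p = 0.36, 0.36 and 0.986 with an estimated correlation. Adjusted over the list alone, 0 members of these lists passed. The 3 lower lists fell most between the discordant libraries. Mean log2 CPM went from 7.28 to 5.74 for the respiratory chain, 9.45 to 7.46 for ribosomal proteins and 6.71 to 5.66 for antioxidant enzymes. The next largest falls, in replicate 2, were from 6.85 to 6.51, 10.6 to 10.2 and 5.51 to 5.23, and the ribosomal mean rose slightly in replicate 4. NRF2 targets were not called in any of the 4 comparisons, with or without the block. The inflammasome list was called, lower, only at 1 nM with the block (adjusted p = 0.0323, and adjusted p = 0.179 with an estimated correlation). Other calls gained with the block were NF-kB and clock genes, higher, and MHC class II, lower, in vehicle against untreated. At 1 nM the block added hypoxia, lower, and macrophage identity and MHC class II, higher, and lost red cell genes. At 1000 nM it added glycolysis, cell cycle, macrophage identity and MHC class II, higher, and lost antioxidant enzymes, aryl hydrocarbon receptor targets, metallothioneins and trophoblast genes. Between the doses it added NF-kB, glycolysis, hypoxia and cell cycle genes, higher, and lost respiratory chain genes. Members that passed with the block were 2 interferon genes and 1 MHC class II gene in vehicle against untreated, 1 and 1 at 1 nM and 1 interferon gene at 1000 nM. Without the discordant libraries, NF-kB genes (adjusted p = 0.00566 with an estimated correlation) and interferon genes (adjusted p = 0.00354 with an estimated correlation) were higher in vehicle than untreated. NF-kB genes (adjusted p = 0.00392 with an estimated correlation) and interferon genes (adjusted p = 0.00242 with an estimated correlation) were lower and alternative activation genes (adjusted p = 0.00922 with an estimated correlation) higher at 1 nM than in vehicle. Interferon genes were also lower at 1000 nM (adjusted p = 0.00448 with an estimated correlation). With the block as well, the NF-kB call at 1 nM held with an estimated correlation (adjusted p = 0.0414 with an estimated correlation) and the other 5 did not. Only 4 NF-kB and 4 interferon genes reached 10 CPM in JEG-3 outside the discordant libraries. There 3 alternative activation, 1 macrophage identity and 0 MHC class II genes did, so calls of these lists may rest on few reads or on the discordant libraries.

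**Figure D3:**
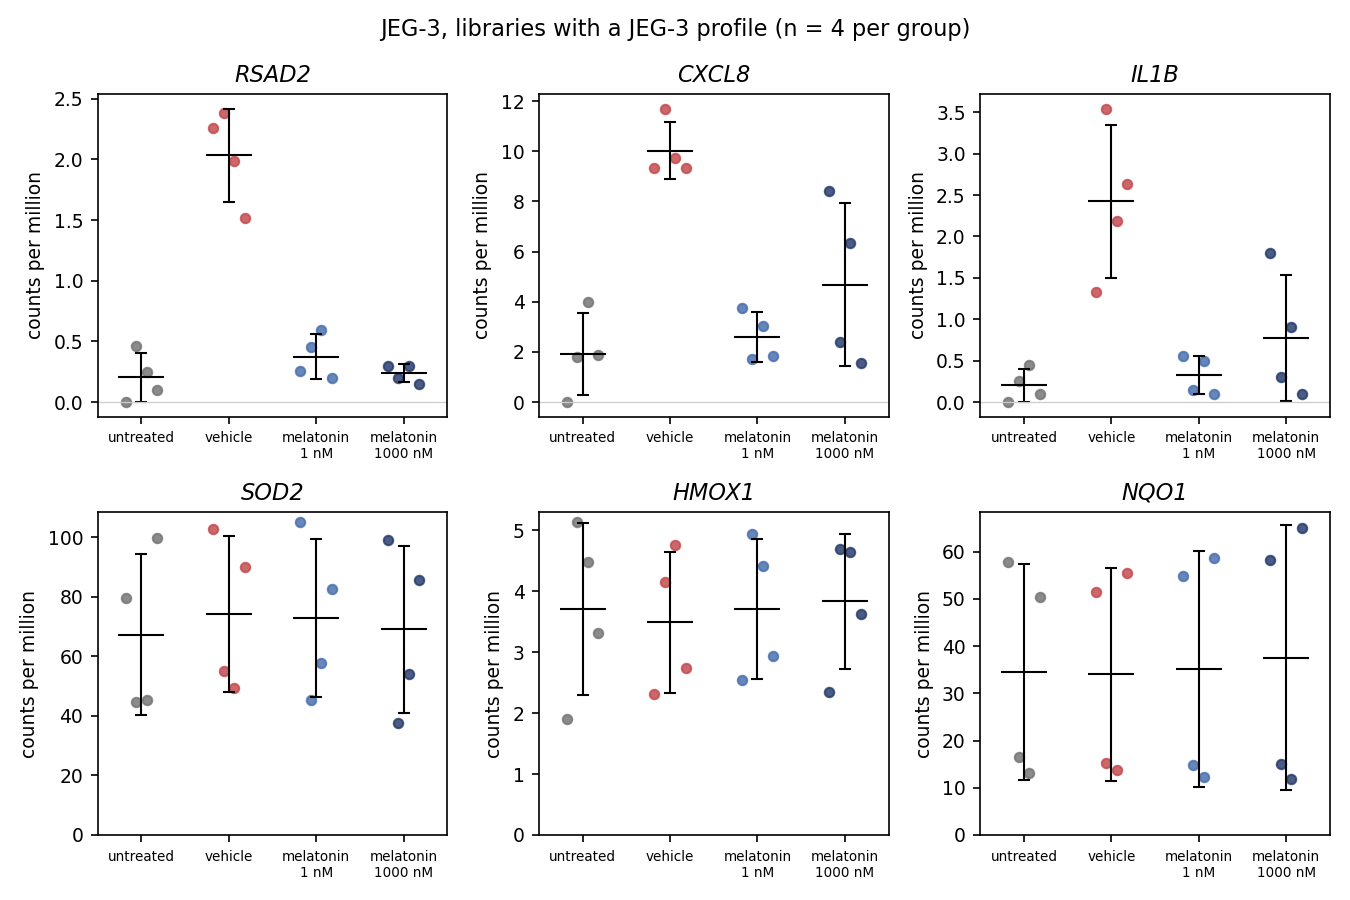
Level in CPM of RSAD2, CXCL8, IL1B, SOD2, HMOX1 and NQO1 in each of the 16 libraries with a JEG-3 profile (points), with the mean (line) and SD (bars, n = 4 per group). RSAD2 is higher in vehicle (mean 2.03) than in the other groups (means 0.20 to 0.375), while SOD2, HMOX1 and NQO1 overlap between groups.

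Untreated JEG-3 and macrophages were compared as a reference for the effects in each. The amino acid transporter SLC6A19 (log2 fold change 11.18 ± 2.26 SE), the collagen COL9A3 (10.93), the endocytic receptor LRP2 (9.94), the tight junction protein CLDN6 (9.36) and the pluripotency factor ZFP42 (9.16) were higher in JEG-3. So were the DNA methylation enzymes DNMT3B (8.76) and TET1 (8.62), the protease CTSV (8.48) and glycine decarboxylase GLDC (8.31). The receptor GPR34 (-7.80 ± 1.69 SE), the scavenger receptors STAB1 (-6.74) and CD36 (-5.69), the selenium carrier SELENOP (-6.22), CD93 (-5.38), thrombomodulin (THBD, -5.26), the lysosomal fucosidase FUCA1 (-5.04) and the efferocytosis receptor MERTK (-4.71) were lower. LIN28A, a regulator of let-7 microRNAs, stood at 137 ± 12.97 CPM in the 4 untreated libraries with a JEG-3 profile and 0.0253 ± 0.0507 CPM in macrophages. Of 14305 genes 5422 passed, 3661 higher and 1761 lower in JEG-3, and 10570 of 14278 without the discordant libraries, 4956 higher and 5614 lower. Leaving out the discordant untreated library alone gave 9619. The fold changes above come from the fit of all libraries, which counts that library as JEG-3. Of 21 named genes that passed in it, 16 passed in every fit without 1 library. CD36 passed in 5 of 9 such fits and CD93 in 2 of 9.

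Among the preset genes TXNRD1 was lower in JEG-3 with and without the discordant libraries (-1.01 and -0.90). NLRP3 (-2.66 and -5.51), CASP1 (-0.47 and -8.39), HMOX1 (-3.21 and -7.78) and SOD2 (0.068 and -5.06) passed only without them, and IL1B went from 1.00 to -10.20. All 26 cell cycle genes (median 4.46, adjusted p = 1.26e-12) and all 36 ribosomal protein genes (median 2.04, adjusted p = 2.03e-15) were higher in JEG-3, as were 17 of 28 trophoblast genes (adjusted p = 0.00513), such as the hormone subunit CGA (7.43). Macrophage identity genes were lower (2 of 22 passing, and 22 of 22 without the discordant libraries; adjusted p = 2.46e-05). In all 18 lists were called, 6 higher and 12 lower, and none held with an estimated correlation: adjusted p = 0.668 with an estimated correlation for each of these 4. Among lists 16 were called without the discordant libraries, and the lower inflammasome and NRF2 lists held (both adjusted p = 0.00286 with an estimated correlation).

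The difference between the cell types in the melatonin effect was tested as an interaction. With all libraries 0 genes passed for 1 nM by edgeR (167 at an unadjusted p below 0.05) and 0 for 1000 nM (144), with 2 and 1 by DESeq2 and 665 and 538 with the replicate block. Without the discordant libraries 46 passed for 1 nM and 17 for 1000 nM, and 2373 and 2015 with the block. Leaving out the discordant vehicle library alone gave 1 gene at each dose. The genes named for this smaller set were chosen after their values were seen. At 1 nM the kinase LIMK2 (2.31 ± 0.31 SE, adjusted p = 6.02e-04), the Notch ligand DLL1 (2.88), the zinc transporter SLC39A8 (3.03), LSS (1.55), RELB (1.75) and SOD2 (2.17, adjusted p = 0.0388) had a higher value in JEG-3 minus macrophage. FFAR4 (-4.39), SLC46A1 (-2.36), ABCG2 (-1.86) and the receptor TGFBR1 (-1.11) had a lower one. At 1000 nM LIMK2 (2.09), SLC39A8 (2.58), MCOLN2 (4.38) and LSS (1.39) were higher and SLC46A1 (-2.23), TGFBR1 (-1.03) and ABCG2 (-1.85) lower. With untreated in place of vehicle and without the discordant libraries, edgeR called 0 at both doses (40 and 68 at an unadjusted p below 0.05).

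At 1 nM the interaction lists called with all libraries were NF-kB genes, immediate early genes and metallothioneins, higher, and neutrophil markers, lower; at 1000 nM aryl hydrocarbon receptor targets took the place of metallothioneins. The NF-kB list, of which 0 of 24 members passed, also when adjusted over the list alone, had adjusted p = 2.27e-04 and 2.34e-05 at the doses, and adjusted p = 0.975 and 0.961 with an estimated correlation. Of the other calls none held, with adjusted p from 0.114 to 0.975 with an estimated correlation. At each dose 4 lists were called without the discordant libraries, and adjusted p was from 0.347 to 0.777 with an estimated correlation.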

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

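Chosen only after the results were seen were leaving out the discordant libraries, the tests of a swap and of an outside preparation, and those of a countered diluent effect and of a stimulus missing from the melatonin libraries. Within the 8 groups, 9 measures were compared by Dixon's test: library total, genes with counts, the share of the 50 most abundant genes and 6 list scores. A score is the mean log2 CPM of a list's members. In 23 of the 72 tests a library stood apart from its group. Chance gives about 1 in 20 groups, 3.6 here, and 20 of the 23 came from the discordant JEG-3 libraries.

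In the discordant library of the untreated group the scores were 4.99 for the inflammasome, 8.67 for NF-kB genes, 8.16 for NRF2 targets, 6.71 for antioxidant enzymes and 7.97 for macrophage identity, each above the other 4. In that of the vehicle group they were 5.44, 8.72, 7.80 and 7.18 for the inflammasome, NF-kB, NRF2 and macrophage identity lists, with 14326 genes detected. At 1 nM they were 5.04, 8.20, 7.94 and 7.95 with 14324 genes, and at 1000 nM 5.35, 8.78, 8.02 and 8.03 with 14353 genes.

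The discordant libraries hold almost no JEG-3 transcripts, the highest of their medians being 0.435% of the JEG-3 level, within what macrophage libraries show (up to 0.762%). That argues against JEG-3 cells mixed with macrophage RNA, which would leave JEG-3 transcripts. A swap inside the series would need a macrophage label on a JEG-3 library, and 0 of the 16 libraries labelled macrophage were closer to JEG-3. A macrophage preparation outside the 16 libraries, carried under JEG-3 labels, stays open as a candidate explanation: the lowest median correlation of the 4 with macrophage libraries was 0.901, inside the range between macrophage replicate numbers (0.85006 to 0.974), against at most 0.570 with JEG-3. No biological explanation was tested.

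In macrophages the NF-kB score stood apart in 1 untreated library (3.87, others from 5.79 to 5.96), 1 vehicle library (10.5, others from 7.25 to 7.45) and 1 library at 1 nM (4.42, others from 5.74 to 5.87). Without those of the 2 groups compared, the difference in mean score shrank from 2.78 to 1.49 for vehicle against untreated, from -2.69 to -1.55 at 1 nM and from -2.36 to -1.57 at 1000 nM. It turned from 0.42 to -0.076 for 1000 nM against untreated and from 0.33 to -0.015 for 1000 against 1 nM. For 1 nM against untreated it turned from 0.093 to -0.061. Only this last comparison lost a whole replicate pair, number 4, so its sign hangs on that pair. In the other 2 the 1000 nM library of number 4 stayed in, which also scored low (4.86). Those 2 sign changes part a pair and cannot show that the sign hangs on 1 library. Between the doses the score was higher at 1000 nM in 4 of 4 pairs. The comparisons with vehicle part pairs too. The check without these libraries and the counts of pairs by direction were added after the results were seen.

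In macrophage vehicle libraries the inflammatory rise could come from several sources. Library scaling is argued against by an NF-kB list median of 3.56 under TMM and 3.60 with DESeq2 size factors. A larger share of other cells stays open, although medians for stroma, endothelium and T and natural killer markers were unequal (0.258, 0.0582 and 0.602), as was set in advance to exclude it, because only 2 of 8 endothelial and 1 of 15 T and natural killer genes reached 10 CPM. A stimulus in the vehicle libraries that the melatonin libraries did not receive also stays open: libraries at 1 nM showed at most 8.03% of the vehicle effect (mean 2.98 ± 3.65% SD, n = 4), but those at 1000 nM up to 33.6% (mean 13.5 ± 15.2% SD, n = 4). That melatonin counters an effect of the diluent cannot be told apart from it: the share at 1000 nM was higher by 10.6 percentage points (SD 14.9) in 4 of 4 pairs, the opposite order to a countering that grows with dose, but 4 pairs cannot give an exact two-sided p below 0.125.

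JEG-3 vehicle libraries outside the discordant set held reads of inflammatory and interferon-induced genes such as IL1B and RSAD2. Across 3288 genes below 1 CPM in untreated JEG-3, which are not independent, the vehicle minus untreated difference correlated with that in macrophages at r = 0.569 (rho = 0.153, and r = 0.248 to 0.384 within replicates), at 0.0397% of its size. Carry-over of a few reads or molecules from the macrophage vehicle libraries may account for it, but r lies between the values above 0.7 and below 0.2 set in advance for carry-over and for its absence, so the data cannot tell. For a response of the JEG-3 cells themselves, the 4 NF-kB genes at 10 CPM or more in untreated JEG-3 were tested. Their median log2 fold change was 0.0733 (0.0306 to 0.369), below the 0.2 set in advance against a response. That level leaves out most of the list, the genes that are low without treatment. The test thus covers these 4 genes only and cannot exclude a response of the others. Interferon-induced genes such as RSAD2 were not part of it, so a response of these in JEG-3 stays open too.

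The difference from vehicle was tested between the cell types as an interaction. With all libraries edgeR gave 0 genes at both doses (167 and 144 at an unadjusted p below 0.05, and 2 and 1 by DESeq2). Without the discordant libraries it gave 46 for 1 nM and 17 for 1000 nM. On that set with untreated in place of vehicle it gave 0 and 0 (40 and 68 at an unadjusted p below 0.05; DESeq2 was not run), so these calls rest on the vehicle libraries and are not shown to be effects of melatonin.

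Other splits of the same libraries show whether chance can be excluded as the source of a count. In macrophages the gene counts for vehicle against untreated (558), 1 nM (461) and 1000 nM against vehicle (202) were each reached by 1 of 35 splits. The highest other count was 0, but most of these splits ignore the replicate pairing. Among the 8 splits that part as many replicate pairs, the block fit gave 4349, 4151 and 3596 for the real split and at most 1, 2 and 0 for the others. The real split stood far above the rest, but 1 of 8 is the smallest share that 4 pairs allow. That share is too large to exclude chance for these counts. Nor can chance be excluded for the macrophage list counts of 10, 9, 10 and 4. These were reached by 18, 20, 16 and 33 of 35 splits, with 16, 17, 14 and 14 as the highest other. With the block JEG-3 gave 7, 6 and 2 genes against at most 3, 1 and 0 among 16 splits that part as many pairs. The smallest share these allow is 1 of 16. Chance cannot be excluded for the JEG-3 lists (4, 6, 7 and 2, reached by 35, 26, 27 and 36 of 40 splits, with 17, 17, 18 and 17 as the highest other). Between cell types it can be excluded (5422, against 4827 as the highest other of 40 splits). The split with 4827 moved 1 JEG-3 library, the discordant one. It thus again set the libraries with a JEG-3 profile against macrophages and is not a count of a random regrouping. A real count of 0 is reached by any split, so the test says nothing of chance for macrophage genes between the doses (35 of 35 splits, highest other 0), for JEG-3 genes in the 4 comparisons without the block (40 of 40, highest other 0) or for the interaction (40 of 40 at both doses, highest other 2 and 23).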

How the results depend on the processing

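Chosen after the data were seen were the settings that drop all 4 discordant libraries, JEG-3 replicates 1 and 4 or 2 and 3 alone, untreated in place of vehicle for the lists, and that control with the replicate block. The others were planned, and leaving out each replicate number in the block fit was among them. Depth limits genes near 1 CPM, which is fewer than 20 reads per library. DESeq2 size factors kept each count of genes or lists within 1.5 times, and so did testing genes without the filter on low counts. Replicate block calls that differ are given in the report and here, and the block changed no other call of a named gene. For lists with all libraries it changed no other call in vehicle against untreated, in the doses against vehicle or between the doses. Where a setting changes the libraries, the control or the threshold, the change follows from that choice. For the other changes the cause was not tested.

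For macrophage vehicle against untreated, 1 nM against vehicle and 1000 nM against vehicle the gene counts were 558, 461 and 202. A minimum absolute log2 fold change of 1 gave 307, 259 and 120. DESeq2 gave 1348, 1290 and 975, and edgeR on only the groups compared 10, 12 and 0. That 0 had 1509 genes at an unadjusted p below 0.05 and was not repeated by DESeq2 on those groups alone. Leaving out 1 library gave from 105 to 500, 90 to 463 and 21 to 252.

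With the replicate block the same 3 counts were 4349, 4151 and 3596. Leaving out 1 replicate number in that fit gave 2224, 2905, 3416 and 4932 for vehicle against untreated. It gave 1992, 2678, 3180 and 4669 at 1 nM. At 1000 nM it gave 1327, 2594, 2615 and 4004.

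Untreated in place of vehicle gave 0 genes at 1 nM and 0 at 1000 nM by edgeR, with 2 and 4 at an unadjusted p below 0.05. With the block as well it gave 0 and 0, with 113 and 145. The mean of both controls gave 1 and 0, with 634 and 384. DESeq2 was not run for these controls. Between 1000 and 1 nM edgeR called 0 macrophage genes (3 at an unadjusted p below 0.05, and 0 by DESeq2), and 0 without any 1 library.

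Macrophage lists called were 10, 9 and 10 for those 3 comparisons and 4 between the doses. An estimated correlation gave 1, 1, 1 and 0 (limma's camera; 5, 4, 5 and 0 at an unadjusted p below 0.05). Against untreated 1 nM gave 4 lists and 1000 nM gave 7, with the block 4 and 7 too, and 0 and 0 with an estimated correlation. Leaving out 1 library gave from 9 to 11, 7 to 10, 6 to 11 and 4 to 11.

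JEG-3 lists called were 4 for vehicle against untreated, 6 at 1 nM, 7 at 1000 nM and 2 between the doses. An estimated correlation gave 0, 0, 0 and 0 (limma's camera; 2, 0, 0 and 0 at an unadjusted p below 0.05, and DESeq2 has no list test). The block gave 7 for vehicle against untreated, 10 at 1 nM and 5 between the doses. Dropping the discordant libraries gave 1 between the doses, and with the block 10 at 1 nM and 4 between the doses. Against untreated 3 were called at 1 nM and 3 at 1000 nM, all lower, and 0 and 0 with an estimated correlation. The block gave 4 and 5 there. Leaving out the discordant libraries gave 6 (3 higher) and 6 (5 higher), and with the block 4 and 6. Leaving out 1 library gave from 3 to 15, 6 to 16, 8 to 17 and 2 to 16, the highest each time without a discordant library.

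JEG-3 gene counts by edgeR were 0 for vehicle against untreated, 0 at 1 nM, 0 at 1000 nM and 0 between the doses. At an unadjusted p below 0.05 there were 192, 9, 10 and 4, and DESeq2 called 0 in each. No library left out alone changed these counts of 0. Replicates 1 and 4 alone gave 0 in each by edgeR (81, 55, 150 and 45 at an unadjusted p below 0.05), and replicates 2 and 3 alone 0 in each (446, 203, 253 and 107); DESeq2 was not run on these subsets of 2 libraries per group. The block gave 7, 6 and 2 for the first 3, and 1, 1 and 1 once the discordant libraries were dropped. Against untreated with the block 1000 nM gave 1 gene, LAMA3. Leaving out 1 replicate number in the block fit gave 1, 31, 34, 52 and 56 for vehicle against untreated. It gave 1, 9, 20, 27 and 30 at 1 nM, and 1, 4, 12, 13 and 19 at 1000 nM. The lowest of each is without the discordant libraries.

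The interaction counts were 0 for 1 nM and 0 for 1000 nM by edgeR, with 167 and 144 at an unadjusted p below 0.05 and 2 and 1 by DESeq2. The block gave 665 and 538, dropping the discordant libraries 46 and 17, and both 2373 and 2015. Leaving out 1 library gave 0 to 1 at both doses. The cell type count of 5422 was 10570 without the discordant libraries, and 4332 to 9619 without 1 library. The correlation between doses was 0.971 in macrophages and 0.851 in JEG-3. With untreated as the control of 1 nM alone it was -0.0980 and -1.04e-05, and with untreated as the control of 1000 nM alone -0.348 and 0.0285.

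For 223 results of named genes, fits without 1 library and block fits without 1 replicate number were counted together. These kept the call in 2248 alternatives, gained it in 116, lost it in 362 and turned the sign in 4. The block changes calls by itself, so these counts do not show the effect of 1 library alone. A change of control kept 184, lost 73 and turned the sign in 77. The other settings kept 1048, gained 49, lost 108 and turned the sign in 4. Between cell types the sign turned for IL1B, IL18, GSDMD and SOD2 without the discordant libraries (-10.20, -2.80, -2.78 and -5.06). It also turned without the discordant untreated library alone (-10.24, -2.84, -2.83 and -5.11), the lowest values without 1 library, against highest values of 1.68, 0.55, 0.85 and 0.41.

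Each of the 77 was a macrophage gene with untreated in place of vehicle, and none passed. At 1 nM these were SLC46A1 -0.021, CEBPA -0.084, TNF 0.053, IDO1 0.11, CCL4 0.14, CCL3 0.037, SLAMF1 0.30, NLRP3 0.090, SOD2 0.066, MEFV 0.10, CASP4 0.027, NFKBIA 0.057, IFIH1 0.26, HK2 0.057. With the block at 1 nM they were CEBPA -0.047, TNF 0.14, IDO1 0.074, CCL4 0.23, CCR7 0.11, IL1A 0.026, EREG 0.025, CCL3 0.13, SLAMF1 0.26, NLRP3 0.092, SOD2 0.074, MEFV 0.071, CASP4 0.027, NFKBIA 0.073, IFIH1 0.30, HK2 0.066. At 1000 nM they were FFAR4 -0.29, CD180 -0.24, CD300LB -0.063, SLC46A1 -0.15, CEBPA -0.22, ABCG2 -0.10, SLC19A1 -0.16, IDO1 0.24, SLAMF1 0.86, GCH1 0.51, CCL8 1.03, IL2RA 0.29, EDN1 0.058, CASP5 0.67, NLRP3 0.12, SOD2 0.41, MEFV 0.084, CASP4 0.022, RELB 0.21, NFKBIA 0.39, CMPK2 0.017, LSS 0.11, HK2 0.14. With the block at 1000 nM they were FFAR4 -0.17, CD180 -0.25, CD300LB -0.080, SLC46A1 -0.13, CEBPA -0.21, ABCG2 -0.088, SLC19A1 -0.17, IDO1 0.30, CCR7 0.085, SLAMF1 0.92, GCH1 0.67, CCL8 0.68, IL2RA 0.29, EDN1 0.10, CASP5 0.74, NLRP3 0.11, SOD2 0.40, MEFV 0.016, CASP4 0.023, RELB 0.20, NFKBIA 0.37, CMPK2 0.068, LSS 0.13, HK2 0.14.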
